A study of Homo sapiens with 10 samples.

How the data were processed

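RNA of A549 cells was amplified with a panel of gene-specific primers for the human transcriptome (AmpliSeq) and read on an Ion S5 XL sequencer, per the labels' protocols. The genome build was hg19, per the submitters' processing notes. How reads were counted, scaled and turned into ratios is not given in the sources used here. The 10 libraries fall into 5 groups of 2 by their titles: untreated, wild-type IFNG, GIFN2, GIFN3 and GIFN4, each with a replicate A and a replicate B. The series describes them as biological replicates.

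Each deposited table holds 1 column of values named log2(DER) per the file headers, in 20812 lines with a name each. The untreated tables are 0 throughout, so the deposited log2 values are read as log2 ratios of a treated library to the untreated library with the same letter. The comparison named in a header does not always match the label of the sample (some read as wild type against untreated, others in the reverse order or as wild type against an analogue). The groups here follow the labels of the samples. Some names had been turned into dates by a spreadsheet (28), and 20810 names were distinct.

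The names and the values in a line are not paired, as the report sets out. For this reason the 24 gene lists fixed for the analysis were not tested and no value is given for a named gene. A panel of single genes fixed for the analysis is in part not reported here. The 3 lists used for the check of the names were MHC class I antigen presentation (21 names found, 16 at 0 in all 8 treated libraries and 0 with a wild type rise of at least 2-fold), guanylate binding and APOL proteins (14, 7 and 2) and antiviral interferon-stimulated genes (46, 42 and 0). Lines are called genes and numbered by position. Some may be spike-in controls, whose names also occur in the files.

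Absolute depth is unknown. The most frequent value other than 0 in a treated library was read as equal read numbers in both libraries of the ratio, which gives the relative depth. Values of a letter were then matched, within 0.0012 on the log2 scale, to whole reads over an untreated number of 10 to 100 reads. These limits were narrowed after a first, wider search had also matched many shifted values. A match was accepted only where its chance was under 0.005. That chance grows with the treated read numbers, so genes with the largest rises cannot be matched and may still have few untreated reads. In letter A 3134 of the 12809 lines not at 0 in its 4 treated libraries matched, and 58 after a random shift of 0.05. In letter B the numbers were 3179 of 12951 and 55. Because 10 was the lowest number tried there, the search was repeated from 1 read with no floor assumed, taking the lowest untreated number that fits. It gave 273 lines in A and 309 in B at 10 untreated reads, against 55 and 56 at 11 and 78 and 118 at 2 to 9 together. Among lines with 11 or more untreated reads, treated values stood at 10 reads 452 and 468 times, at 11 reads 171 and 166 times and under 10 reads 49 and 75 times. The values thus pile up at 10 reads in untreated and treated libraries, as a floor under low read numbers would give, and such a floor would bring the fold change of a gene below it nearer to 0. PCR reads carry no molecular identifiers here, and no counting interval is given.

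Values were compared with limma 3.58.1 in R 4.3.3 (robust empirical Bayes, no trend, Benjamini-Hochberg adjustment, threshold 0.05) over the 13276 genes with a value other than 0 in at least 2 treated libraries. The plan fixed before the data were examined was a count test or limma on log2 levels, over all 10 libraries with no covariate. Ratios allow neither. With the untreated columns at 0, a model with group and letter gives the same estimates as that model on the log2 levels of the 10 libraries, since the letter term absorbs the untreated level, and it accounts for the untreated library that the 4 ratios of a letter share. This model has 4 residual degrees of freedom and was chosen before any call was seen. A fit of the 8 ratios on group alone is the alternative without the letter. The letter is a block because of how the ratios are built. The labels tie no batch or day to it. The deviations of A from B correlated between wild type and the analogues at 0.182 (GIFN2), 0.161 (GIFN3) and 0.0296 (GIFN4), and at 0.650 to 0.700 between analogues.

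There were 10 comparisons: 4 with untreated cells, 3 with wild type and 3 between analogues. The share of the wild type response is the slope through the origin of an analogue's log2 changes on those of wild type over genes raised at least 2-fold by wild type, per letter and fitted. The departure test asked whether an analogue's change differed from its fitted share times the wild type change, adjusted over the 4710 genes changed by wild type. The share came from rises and was applied to falls too, and an alternative used the share of the falls for the falls. Apart from those said to be named after their values were seen, the genes given by number are among those the rule fixed beforehand picked: the largest changes past the threshold with the same direction in both letters, and the smallest p for departures from the share. Its minimum level could not be applied to ratios, and its parts on named genes were void. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.

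The tests were run on simulated ratios of 13276 genes with the residual spread of the real genes, an untreated error shared within a letter and 200 changed genes. For wild type against untreated cells, 2% of changes of 0.5, 44% of changes of 1, 82% of changes of 2 and 98% of changes of 3 log2 units were recovered, with 7 false among 120 calls. The data gave 4710 calls for this comparison, so the adjustment was stricter in the simulation. The recovery rates therefore do not give the power of the reported test. For GIFN4 against wild type, with GIFN4 at a reduced change, 36% of genes with a wild type change of 2 and a difference of 1 were recovered, with 1 false among 51 calls. A further 20 draws gave the analogues letter errors that correlated at a mean of 0.670 between GIFN2 and GIFN4 and 0.127 between wild type and GIFN4, with the spread of each gene taken from its differences between letters. Alternatives were the fit without the letter, other filters, a minimum change of 2-fold, fits on 2 groups, each library left out in turn, other summaries of the share and, chosen after seeing the data, median centring, a non-robust fit, genes with values other than 0 in all 8 treated libraries, and leaving out 3894 tested genes with few reads (a read number recovered as above, a 0, or a value equal to that of wild type), or 3814 without the rule on equal values.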

Results

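Transcript levels were measured in A549 cells, a human lung cancer cell line, that were left untreated or given 1 of 4 proteins for 48 h: wild-type interferon gamma (IFNG), the cytokine that signals through the IFNGR1 and IFNGR2 receptor chains, or 1 of 3 proteins named GIFN2, GIFN3 and GIFN4, which the series title calls partial agonists. The recorded dose was 62 nM for all 4 proteins. It is written with a point and no digit after it, so a digit may be missing. Each of the 5 groups had 2 libraries, lettered A and B and described as biological replicates, which makes 10 libraries. The files give each treated library as log2 ratios to the untreated library of the same letter, over 20812 lines. Between 12835 and 13137 lines per treated library held a value other than 0, and 7414 lines were at 0 in all 8 treated libraries. The absolute read depth of the libraries is unknown. Their depth relative to the untreated library of the same letter, read from the most frequent value other than 0 as equal read numbers in both libraries, ran from 0.882 in wild type A to 1.27 in GIFN3 B.

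The values could not be assigned to gene names. In wild type A the values never rose from any line to the next, whereas the names beside them ran in alphabetical order at 99.8% of the first 450 lines, so the order of the values did not follow the order of the names. Of 81 names from 3 lists of interferon target genes, 65 stood beside a 0 in all 8 treated libraries, where 35.6% of all lines were at 0 in all 8. So did the 6 names IRF1, CD274, IDO1, HLA-B, CXCL10 and GBP1, chosen for this check from the fixed lists. These 6 include the transcription factor IRF1 and the immune checkpoint ligand PD-L1 (CD274). Of the 81 names, 2 stood beside a mean wild type rise of at least 2-fold, APOL2 and APOL5, which stand on consecutive lines. Such a rise was found in 3.88% of all lines. The lines themselves matched between files. Over the lines tested, which are not independent replicates, the Pearson correlation of any pair of treated libraries lay between 0.751 and 0.947, and the highest value for wild type A and B over 1000 shuffles of the lines was 0.0273. Each line is therefore treated as a gene of unknown name, numbered by its position in the files, and no gene list is tested.

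The first question was how A549 cells responded to wild-type IFNG. Of 13276 genes tested, 2066 were higher and 2644 were lower than in untreated cells at an adjusted p under 0.05 (limma), of which 788 rose and 1094 fell at least 2-fold. With each library centred on its median, chosen after seeing the data, 2328 were higher and 2427 lower, so the excess of falls depended in part on the scaling. The response reached far at its upper end: 106 of the genes called rose by 3 or more on the log2 scale, 47 of them by 4 to 6 and 12 by over 6. Gene 1 had a log2 change of 9.51 ± 0.20 (SE, n = 2; adjusted p = 5.26e-06, limma), with 9.97 in A and 9.06 in B, and gene 2 had 8.30 ± 0.17 with 8.29 and 8.30. The falls were smaller, with gene 20812 at -5.09 ± 0.27 and gene 20811 at -5.01 ± 0.13, the latter a gene with few reads in some library, whose size of change is uncertain. The rule for few reads cannot reach the largest rises, so genes 1 and 2 may also rest on few untreated reads. The files are sorted by wild type A, so these positions follow from its values. Wild type A and B differed by a median of 0.27 on the log2 scale. Leaving out untreated A or untreated B lowered the count of changed genes from 4710 to 2614 or 2432, and a fit on wild type and untreated libraries alone gave 2923.

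All 3 analogues changed many genes in the same cells. GIFN2 raised 1966 and lowered 2236 genes, GIFN3 raised 2051 and lowered 2157, and GIFN4 raised 1721 and lowered 1532 (limma, adjusted p under 0.05). With each library centred on its median, chosen after seeing the data, GIFN4 raised 1651 and lowered 1716, so which direction held more genes depended on the scaling. At least 2-fold changes numbered 731 rises and 885 falls under GIFN2, 744 and 843 under GIFN3, and 624 and 459 under GIFN4. Gene 1 again led the rises, at 8.06 ± 0.20 under GIFN2, 8.04 ± 0.20 under GIFN3 and 6.56 ± 0.20 under GIFN4 (SE, n = 2), and gene 20811 the falls, at -4.92 ± 0.13, -5.04 ± 0.13 and -3.81 ± 0.13. Gene 20811 is dropped when genes with few reads are left out, and its value in GIFN2 A equals that in wild type A (-5.07), so its falls are near the low-read limit and not exact. Without GIFN2 A, GIFN2 B, untreated A or untreated B the GIFN2 count of 4202 became 2172, 1982, 2172 or 1990. Without GIFN3 A, GIFN3 B, untreated A or untreated B the GIFN3 count of 4208 became 1878, 1899, 2120 or 1962, and without GIFN4 A, GIFN4 B, untreated A or untreated B the GIFN4 count of 3253 became 1332, 1242, 1146 or 1097. A fit on GIFN4 and untreated libraries alone gave 1751.

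The genes called under the analogues were largely those called under wild-type IFNG. Of the 2066 genes higher under wild type, 1646 were also called higher under GIFN2, 1734 under GIFN3 and 1358 under GIFN4, where independent lists of these sizes would share 306, 319 and 268. Of the 2644 lower genes, 2019, 1979 and 1405 were shared, against 445, 430 and 305. Fitted log2 changes correlated across genes with those of wild type at r = 0.946 for GIFN2, 0.949 for GIFN3 and 0.868 for GIFN4. These comparisons share the untreated libraries, and simulated groups with no change gave r = 0.503, 0.502 and 0.501 and a mean of 0 shared calls over 20 draws. These r values follow from giving every library errors of equal size. With no true change hardly any gene can be called, so the 0 does not measure the overlap that shared libraries add. The covariances were 0.615, 0.613 and 0.470, against simulated values of 0.0299, 0.0298 and 0.0298. Wild type A set against the analogue's B library, which share no untreated library, gave r = 0.854, 0.863 and 0.796, and wild type B against the analogue's A library 0.877, 0.879 and 0.777. Part of the overlap of calls may still come from the shared untreated libraries. Opposite calls were limited to genes 16338, 16695 and 17089, named here after their values were seen, which were lower under wild type (-0.43, -0.39 and -0.47) and higher under GIFN4 (0.62, 0.88 and 0.39). Without untreated A their wild type falls had adjusted p = 0.0815, 0.172 and 0.0824 (limma), without untreated B 0.235, 0.136 and 0.0638, and with each library centred on its median, chosen after seeing the data, each lost the call under wild type or GIFN4.

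The size of the response was next set against that of wild type, over the 788 genes that rose at least 2-fold under it. GIFN2 reached 85.5% of the wild type log2 change in A and 83.0% in B, GIFN3 86.4% and 84.9%, and GIFN4 67.6% and 66.4%. Over the 1094 genes that fell, GIFN2 reached 82.4% and 91.3%, GIFN3 78.7% and 87.8%, and GIFN4 53.7% and 64.1%. GIFN4 minus GIFN2 was thus -18.0 and -16.6 points among the rises in A and B, and -28.7 and -27.2 points among the falls, each larger in size than the gap between the letters of either protein. GIFN3 minus GIFN2 was 0.88 and 1.87 points among the rises and -3.76 and -3.54 points among the falls. The libraries were not centred for these values. Their medians were -0.096 in wild type A, 0.044 in GIFN2 A and 0.0845 in GIFN4 A, against -0.022, -0.04 and -0.0175 in B. Such offsets move the shares of rises and falls in opposite directions, and shares of the falls were not computed with centring. The size of these gaps and the differences between letters therefore depend in part on the scaling. With 2 libraries against 2, no exact test can give a two-sided p below 0.333, so no p is attached to these shares. The level of the shares depended on how they were measured. The following values differ from those above in the choice of genes, the letter and the summary at once, so none of these can be singled out. As ratios of means, genes that rose at least 2-fold in wild type B gave 93.9%, 95.5% and 77.3% for GIFN2, GIFN3 and GIFN4 when measured in A, and genes that did so in wild type A gave 86.6%, 88.3% and 71.2% when measured in B. An analogue simulated with the full wild type response was measured at 98.7% on average over 20 draws (range 97.8% to 99.3%) with the fitted share.

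**Figure D1:**
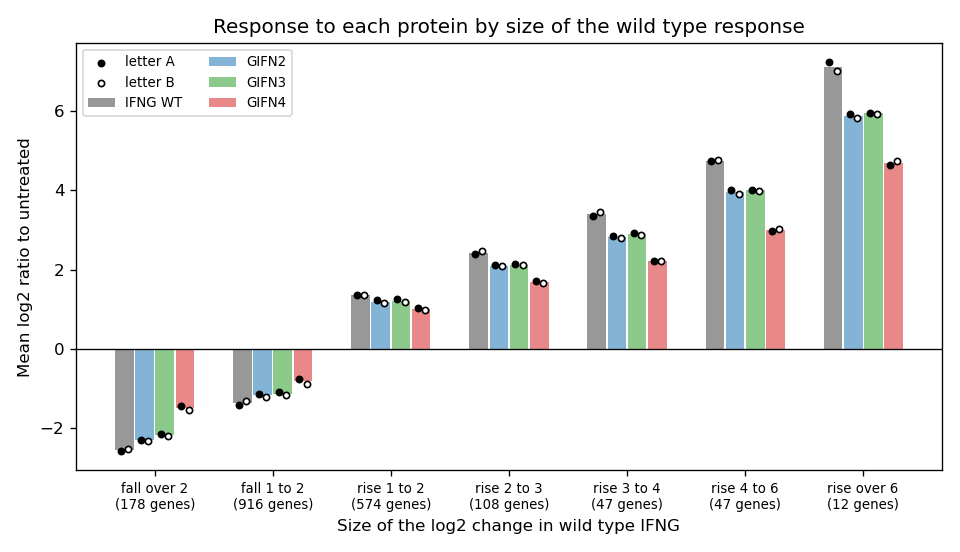
Mean log2 ratio to untreated cells (y axis) for genes grouped by the size of their log2 change under wild-type IFNG (x axis), with a bar for each of the 4 proteins and the letter A and B libraries as filled and open points. GIFN4 lies below the other proteins in size in every group of genes, for example at 4.70 against 7.14 for wild type among the 12 genes that rose by over 6.

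The distance to wild type grew with the size of the response on the linear scale. A constant share of the log2 change below that of wild type gives such a trend by itself, so the trend is no separate result. Among the 574 genes that rose by 1 to 2 log2 units under wild type, the mean log2 ratio was 1.35 ± 0.01 (SD of letters, n = 2) under wild type, 1.19 ± 0.04 under GIFN2, 1.22 ± 0.04 under GIFN3, and under GIFN4 it was 1.03 in A and 0.97 in B. Among the 12 genes that rose by over 6 it was 7.14 ± 0.15, 5.89 ± 0.08, 5.95 ± 0.02 and 4.70 ± 0.07. The geometric mean level under GIFN4 was 78.1% of the wild type level in the first of these groups, 59.9% in the 108 genes with rises of 2 to 3, 43.9% in the 47 with rises of 3 to 4, 29.7% in the 47 with rises of 4 to 6 and 18.5% in the last. GIFN2 went from 89.4% to 42.1% and GIFN3 from 90.9% to 44.0% between the first and the last group. As a share of the wild type log2 change, GIFN4 went from 73.7% to 65.9% over the same groups. The values pile up at 10 reads, and a floor there would limit the ratios of low genes, so these levels are described only relative to wild type.

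No single gene differed between GIFN2 or GIFN3 and wild-type IFNG in the limma test. The count was 0 for GIFN2, with 990 genes at an unadjusted p under 0.05 where chance gives 664, and 0 for GIFN3, with 927. The smallest adjusted p was 0.0531 for GIFN2 and 0.0897 for GIFN3. Among the 788 rises the median log2 difference from wild type was -0.17 for GIFN2 and -0.14 for GIFN3, the 95% interval of a gene reached a median of 0.41 to either side of its estimate, and 72.8% and 76.3% of the genes had an interval within 1 log2 unit of no difference. For GIFN4, which had calls against wild type, this percentage was 59.1%. The margin of 1 log2 unit is wide, since 574 of the 788 genes rose by only 1 to 2 under wild type. GIFN2 lay below wild type in 76.6% of the 788 rises and GIFN3 in 72.1%. The choice of genes by their wild type value alone puts an equal analogue below it in a mean of 56.8% (highest of 20 simulated draws 60.4%, with errors correlated between analogues as observed), so the counts of 0 do not show equal responses. Leaving out genes with few reads, an alternative chosen after seeing the data, gave 12 calls for GIFN2 and 11 for GIFN3, and other such alternatives gave up to 9 calls for GIFN2.

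GIFN4 differed from wild-type IFNG in 561 genes, of which 221 were lower and 340 higher (limma, adjusted p under 0.05), and 139 and 179 of these differed at least 2-fold. Most differed in the direction of the untreated level: 213 of the 221 lower genes were among those raised by wild type, and 287 of the 340 higher genes were among those lowered by it, which is 96.4% and 84.4%. The 287 include genes 16338, 16695 and 17089, which lay beyond the untreated level under GIFN4. Both comparisons use the wild type libraries, so chance alone gives part of this. For an analogue simulated with no difference from wild type, as many genes with the smallest p gave means of 29.5% and 31.0% (highest of 20 draws 34.4% and 36.5%). The largest deficits among genes that passed were in gene 9, at -3.84 ± 0.16 (SE, n = 2; adjusted p = 0.00114, limma), which rose by 6.49 under wild type and 2.65 under GIFN4, and in gene 2, at -3.55 ± 0.17. The largest positive differences were in genes 20812 and 20807, at 2.97 ± 0.27 and 2.75 ± 0.29, which fell by less under GIFN4 and had adjusted p = 0.0519 and 0.0527 (limma) without GIFN4 A. Among the 788 rises, GIFN4 was called below wild type in 190 and above it in 1 (gene 496, named after its values were seen, with 1.08 under wild type and 1.94 under GIFN4). The call of gene 496 was lost without the letter in the fit (adjusted p = 0.146, limma), with median centring (0.0913) and without untreated A or B (0.108), GIFN2 A or B (0.104), GIFN3 A or B (0.0944), GIFN4 A (0.202) or GIFN4 B (0.220). Without the replicate letter in the fit 180 genes were called, all of them among the 561, and a fit on the GIFN4 and wild type libraries alone called 0, with 1 residual degree of freedom. Leaving out a library gave 293 calls without GIFN2 A or B, 272 without GIFN3 A or B, 101 and 129 without GIFN4 A and B, 225 without untreated A or B, 413 without wild type A and 1739 without wild type B, and centring each library on its median, chosen after seeing the data, moved the share of lower calls from 39.4% to 49.8%. The deviations of A from B correlated at 0.650 to 0.700 between analogues and at 0.0296 to 0.182 between wild type and the analogues, so the replicate error was not shared evenly by the groups compared. The SE of GIFN4 against wild type may thus be too small and the 561 calls too many.

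Between the analogues, GIFN4 differed from both others and GIFN2 and GIFN3 were not told apart. The model gave all comparisons the same median SE of 0.17, although deviations of A from B correlated at 0.650 to 0.700 between analogues. The SE may thus be too large for comparisons between analogues and too small for those of an analogue with wild type. Their counts and intervals are not comparable with those against wild type. GIFN3 against GIFN2 gave 0 genes in limma, with 498 genes at an unadjusted p under 0.05 where chance gives 664, and 89.4% of the tested genes had a 95% interval within 1 log2 unit of no difference. The same percentage was 83.84% for GIFN4 against GIFN2 and 84.85% for GIFN4 against GIFN3, so it hardly separates these pairs. GIFN4 against GIFN2 gave 139 genes, 48 lower and 91 higher, of which 45 and 86 were raised and lowered by wild type in turn. GIFN4 against GIFN3 gave 50 genes, 29 lower and 21 higher, and all 29 and 21 were raised and lowered by wild type in turn. Gene 50 had a log2 difference of -3.15 ± 0.31 (SE, n = 2; adjusted p = 0.0206, limma) between GIFN4 and GIFN2 and -2.67 ± 0.31 between GIFN4 and GIFN3. Gene 50 is dropped when genes with few reads are left out, so the size of its difference is uncertain. Its log2 ratio was 4.13 under wild type, 4.01 under GIFN2, 3.53 under GIFN3 and 0.87 under GIFN4, the last with an adjusted p of 0.0943 against untreated cells (limma). Gene 20786 showed the largest positive difference between GIFN4 and GIFN2, at 2.55 ± 0.21. These counts depended on the fit and on single libraries: without the replicate letter in the fit they became 15 and 0, in fits on the 2 groups alone 0 and 0, and leaving out A or B of untreated, GIFN2, GIFN3 or GIFN4 gave 0 for both, whereas leaving out wild type A or B gave 245 and 86.

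The last comparison asked whether single genes kept more or less of the wild type response than the analogue's share over the 788 rises, among the 4710 genes changed by wild type. Under GIFN4, 304 genes departed from its share of 67.5% (limma, adjusted p under 0.05). Of the genes raised by wild type, 97 kept more and 66 kept less. Of those lowered by it, 35 kept more and 106 kept less, but this split follows in part from a share taken from rises, since the GIFN4 share over genes that fell at least 2-fold was 59.8%. With that share applied to the lowered genes, an alternative chosen after seeing the data, 294 genes departed, and 59 of the lowered genes kept more and 72 kept less. Both shares are without centring of the libraries, so these splits may also depend on the scaling. Falls that end at a read floor would be equal under wild type and GIFN4 and would count as kept more. Gene 20780 had -3.15 in every treated A library and -3.24 in every treated B library. GIFN4 equalled wild type in 274 lines in A and 297 in B. How many of the lowered genes that kept more lie at such a floor was not counted. Gene 46 rose by 4.26 under wild type and 4.46 ± 0.12 under GIFN4 (SE, n = 2; adjusted p of the departure 0.00799, limma), and gene 71 by 3.53 and 3.51 ± 0.12. Gene 103, which is dropped when genes with few reads are left out, rose by 2.95 under wild type and had 0.28 ± 0.14 under GIFN4, and gene 9 rose by 6.49 and 2.65 ± 0.16. Of the 106 genes that rose by 3 or more under wild type, 7 were within 0.5 log2 units of wild type under GIFN4 in both letters, 69 were lower by at least 1 and 24 by at least 2. The corresponding numbers were 26, 20 and 0 under GIFN2 and 25, 19 and 0 under GIFN3. In simulated data in which every gene kept 67% of its wild type change, the mean number of departures was 0.05 and the highest of 20 draws was 1 with errors shared through the untreated library, and 0.30 and 2 with errors correlated between analogues as observed. These simulations held no read floor. No gene departed from the share under GIFN2 or GIFN3 in limma, with 531 and 481 genes at an unadjusted p under 0.05. Chance gives a fraction of 0.05 of the 4710 tested, which is fewer. The counts of 0 therefore do not show that every gene kept the same share under GIFN2 or GIFN3. Without the replicate letter in the fit the GIFN4 count was 18, and leaving out a library gave 130 without GIFN2 A or B, 102 without GIFN3 A or B, 9 and 0 without GIFN4 A and B, 168 and 170 without untreated A and B, and 969 without wild type B.

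**Figure D2:**
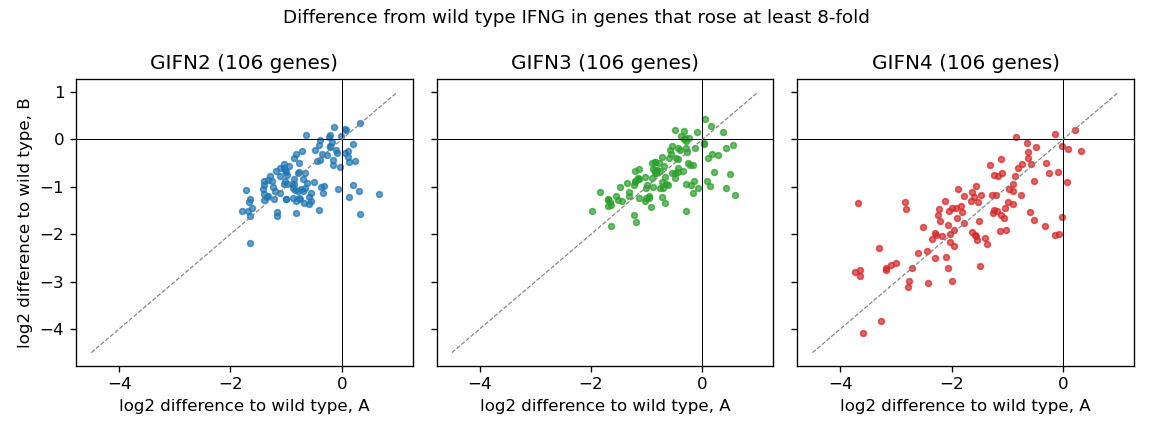
Log2 difference from wild-type IFNG in the letter A libraries (x axis) and in the letter B libraries (y axis) for GIFN2, GIFN3 and GIFN4, with each of the 106 genes that rose by 3 or more on the log2 scale under wild type as a point and the dashed line marking equal differences. Under GIFN4 the points spread along that line, with medians of -1.56 in A and -1.54 in B, against -0.76 and -0.91 under GIFN2 and -0.67 and -0.75 under GIFN3.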

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

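The alternatives with median centring, without the robust option, with values in all 8 treated libraries, with few-read genes left out (with and without the rule on equal values) and with the share of the falls applied to the falls were chosen after seeing the data; the others were planned. No share reversed its sign. Among single genes, 3 values did, none past the threshold: against untreated under GIFN4, gene 108 (log2 change 0.098) became -0.026 without untreated A and -0.14 without GIFN4 A, with a range of -0.14 to 0.34 over libraries left out, and gene 316 (-0.092) became 0.010 without GIFN4 B, with a range of -0.19 to 0.010. Both genes have few reads. Gene 316 in GIFN4 A and B and gene 108 in GIFN4 B stood at the most frequent value of the library (0.010 in A and -0.19 in B), which is read as equal read numbers, so the sign of these values follows the relative depth. Median centring turned GIFN4 against untreated from more genes higher (47.1% lower) to more genes lower (51.0%), and GIFN3, above GIFN2 in its share of the rises, lay below it over genes that fell. Where a cause is not named, the cause was not tested. Absolute depth is unknown. Values of low genes pile up at 10 reads, and a floor there would limit their ratios, a limit no value here measures. Alternatives that need read counts or levels were not run, because the values are ratios: other size factors, total count and upper quartile scaling, a filter on normalised level, DESeq2, voom, other pseudocounts and all list tests.

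Without the replicate block (the letter left out of the fit) GIFN4 against wild type gave 180 genes instead of 561, GIFN4 against GIFN2 15 instead of 139, GIFN4 against GIFN3 0 instead of 50, and departures under GIFN4 18 instead of 304. It changed no other count by over 1.5 times. Fits on the 2 groups compared, with 1 residual degree of freedom, gave 0 for all 3 of these comparisons, 2923 instead of 4710 for wild type against untreated and 1751 instead of 3253 for GIFN4 against untreated. Asking for a 2-fold change, which can only lower counts, left 1882 (wild type), 1616 (GIFN2), 1587 (GIFN3) and 1083 (GIFN4) against untreated, and 318 for GIFN4 against wild type.

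GIFN2 against wild type, at 0 in the reported fit, gave 9 genes with median centring, 12 with few-read genes left out, and 3 each without the robust option and with values in all 8 treated libraries (genes 5, 9 and 41 in both, named after their values were seen). GIFN3 against wild type gave 11 with few-read genes left out. Without the rule on equal values these counts were again 12 and 11, departures under GIFN2 1, GIFN4 against GIFN3 78, and the shares of GIFN3 and GIFN4 87.8% and 71.2%. With the share of the falls applied to the falls, departures under GIFN4 were 294 and those under GIFN2 and GIFN3 0. Departures under GIFN2 rose from 0 to 1 (gene 19697, named likewise) with few-read genes left out and when tested over genes changed at least 2-fold by wild type.

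The shares of the wild type response, 84.8%, 86.2% and 67.5% for GIFN2, GIFN3 and GIFN4, became 82.8%, 84.0% and 64.9% with median centring, 88.9%, 90.9% and 74.7% as medians of the ratios per gene, and 88.1%, 84.5% and 59.8% over genes that fell, the last without centring. They became 93.9%, 95.5% and 77.3% for genes chosen on letter B and measured on letter A, and 88.3% for GIFN3 and 71.2% for GIFN4 with the letters exchanged. On the linear scale GIFN2 had 82.8% and GIFN4 62.5%. Over rises of at least 4-fold GIFN3 had 85.0% and GIFN4 65.5%, and with few-read genes left out 87.8% and 71.2%. GIFN4 had the lowest share in each.

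Leaving out each library in turn, where the lone library is assumed to vary like the other groups, gave 2432 to 5354 genes for wild type against untreated, 1982 to 5489 for GIFN2, 1878 to 5582 for GIFN3 and 1097 to 4662 for GIFN4. It gave 101 to 1739 for GIFN4 against wild type, 0 to 245 for GIFN4 against GIFN2, 0 to 86 for GIFN4 against GIFN3 and 0 to 969 departures under GIFN4. The shares ran from 81.7% to 85.6% (GIFN2), 83.3% to 86.5% (GIFN3) and 65.5% to 68.1% (GIFN4). The counts of 0 stayed at 0. The next counts cover all alternatives in which single genes were followed, not only libraries left out. For the genes given by number and the others the rule picked, 1957 values kept their direction and side of the threshold, 282 no longer passed it, 17 newly passed it and 3 changed direction. Single genes were not followed under the 2-fold setting or the other summaries of the share, and departures not in fits on 2 groups.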

Other observations

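All tests in this part were chosen after the results they concern had been seen. Genes that lost most of the response under GIFN4 also lost more under the other analogues. The 226 genes that rose by 2 or more in wild type A were ranked by the share that GIFN4 A reached and divided into 3 parts of similar size, and all other values were read in the B libraries. In the 75 genes that lost most (40.0% of wild type in GIFN4 A), GIFN4 B reached 49.1% of wild type B, GIFN2 B 73.1% and GIFN3 B 73.9%. In the middle 75 the values were 67.8%, 84.0% and 86.5%, and in the 76 that lost least 83.9%, 92.0% and 93.9%. The mean log2 ratio of wild type B was 3.27, 3.68 and 2.84 in these parts, so their order does not follow the size of the wild type response.

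The unequal loss under GIFN4 was tested over the 106 genes that rose by 3 or more under wild type. Measurement noise would leave the loss in A unrelated to the loss in B, but after removal of its trend with the size of the rise the correlation across genes was 0.665, above the highest of 1000 shuffles (0.339). The loss was unequal under the other analogues too, at 0.468 for GIFN2 (highest shuffle 0.279) and 0.540 for GIFN3 (0.326). With the genes flagged for few reads left out, the value for GIFN4 was 0.701 over the 78 genes left, where the rule on values equal to wild type alone removed 0 of the 106. This argues against the flagged genes as the whole cause. The loss is a difference between ratios to the same untreated library, so untreated reads cancel in it. They enter only through the choice of genes and the trend that was removed. The rule can miss genes with high read numbers in some treated library, so few reads under GIFN4 among the 78 genes are not excluded. The loss of GIFN4 in A also correlated with the loss of GIFN2 in B, at 0.518 against a highest shuffled value of 0.311. GIFN2 in A with GIFN4 in B gave 0.404 (0.266). With GIFN3 the values were 0.634 (0.300) for GIFN4 in A and 0.432 (0.266) for GIFN4 in B. Genes that differ in their sensitivity to all 3 analogues would give such values. A wild type value that was off alike in both letters would too, since every loss is taken against wild type. That genes differ in sensitivity remains a hypothesis, and no test bears on its mechanism.

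Names and values are not linked in these data. A lack of response of the cells is excluded by 95 genes that rose at least 8-fold in both wild type libraries. Sorting of the values without their names may account for it: wild type A never rises from any line to the next, and 2 of 81 interferon target names stand beside a 2-fold rise. Files with the names in the order of the values would settle which genes the positions stand for. No other biological explanation was tested.

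The deviations of A from B were shared by the analogues and hardly by wild type. Noise of the shared untreated library would reach all 4 ratios of a letter, yet the highest correlation of wild type with an analogue was 0.182, while the lowest between analogues was 0.650, so that library is not the whole cause. A handling or sequencing batch of the analogue libraries that wild type did not share could give this pattern, but no label gives a batch, so it cannot be told apart from a response to the analogues that differed between the replicates. The tests against wild type and between analogues assume that deviations are equally independent in all groups, which these values do not bear out.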
